A study of Mus musculus with 8 samples.

How the data were processed

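Poly(A)-selected RNA of E13.5 mouse kidneys was sequenced from 500 ng of input RNA per library with an Illumina TruSeq kit, per the labels' protocols. There were 4 control libraries (a floxed and a wild type Smo copy) and 4 mutant libraries (Foxd1Cre with a floxed and a null Smo copy). Per the submitters' processing notes, TopHat2 2.0.12, HTSeq and DESeq2 1.4.5 were used with the mouse build mm10 (GRCm38). The gene annotation is not given in the sources used here. Strand use in counting is not given beyond "Unstr" in the name of the deposited data, which may mean counting without strand. Libraries were not pooled.

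The authors deposited 1 table of 23337 genes. Its per-library signal values are gene read counts divided by 1 size factor per library. Every value was a whole multiple of its library's smallest value (100% of values within 0.01 read), so the whole reads were recovered, 10288191 to 13494079 per library. The deposited table also holds mean signal per group, the authors' ratio of means (fold change), its log2, and p-values raw and adjusted. Its column names are those of the older DESeq package, per the file headers. It gave no p-value for 4271 genes at 0 in every library.

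The values were log2-transformed after adding a pseudocount of 1. Genes with a mean of at least 10 over the 8 libraries (13692) were tested by limma 3.58.1 with an intensity trend in R 4.3.3, with genotype as the single term, two-sided, and Benjamini-Hochberg adjustment at 0.05. Recovered reads were tested as alternatives with edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0. A count test was not the main test because the deposited values are normalised. Gene lists were tested with camera at a preset correlation of 0.01, with the correlation estimated per list, and with fry. Before the data were examined, 34 lists with 533 symbols were fixed for renal compartments, signalling pathways and tissues near the kidney, of which 516 were in the table and 426 were tested. None of the symbols of the list of mitochondrial transcripts was in the table, so 33 lists were tested. The test design and most alternatives were fixed at the same time.

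The genes named were set by a rule. It took Smo, Foxd1, Gli1, Ptch1 and Hhip, then the 10 largest changes in each direction among called genes whose groups did not overlap and whose higher group had a mean of at least 50. It also took the 5 smallest adjusted p in each direction, with ties ordered by the unadjusted p, and up to 4 members with the smallest p from each list described. Members are described one by one for 19 of the lists. This choice was made after the values of all members had been seen. The 53 members left out by it held no called gene, and 18 of them changed sign under at least 1 alternative, which happened to none of the 95 genes followed one by one. Bcl2, Mdfic, Lhfpl2 and F2r were named outside the rule, after their values were seen. Myh3, Acta1, Mylpf, Myl1, Tnnc2 and Actc1 were also named outside the rule, for their levels per library only. Older symbols are printed as in the table. Positions came from RefSeq GRCm38.p6, matched by symbol or unambiguous synonym for 23055 genes (98.8%).

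Exons of 25 of the 76 called genes found in GENCODE vM21 overlapped exons of another gene, on the opposite strand for 23, and for 3 the other gene was itself tested. Without strand, reads of such genes cannot be told apart, so their values are uncertain to that extent. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 2.89 to 10.98 over tested genes), so none was the same library sequenced again, which does not show that they came from different animals. The highest of these values lay between controls 2 and 4. Library totals limit the counting error, and the spread between libraries sets the tests.

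The steps were tested on simulated data. Counts for the 13692 genes were drawn from the real means, library sizes and spread, with 200 genes changed. For mutant against control, 34.0% of 50 genes changed by 1.25-fold were called in the right direction, 64.0% at 1.5-fold, 88.0% at 2-fold and 90.0% at 4-fold. Of 148 calls 10 were false, and 1 gene was called when none was changed. In a simulation with a shift of 0.3 in 1 list, that list alone passed of 33. The simulated genes varied independently of each other, while the correlation estimated in the real data reached 0.924 for the skeletal muscle list. So the simulation could not show false list calls that arise from correlated members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

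Alternatives covered the pseudocount, the filter, the scaling, the test, the sample number as a block, leaving out X and Y genes and leaving out each library. Another 5 were chosen after seeing the data: leaving out controls 1 and 2, leaving out the libraries numbered 2, a muscle score or a Y-linked score as covariate, and leaving out genes within 20 Mb of Smo and Foxd1.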

Results

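RNA was sequenced from kidneys of mouse embryos at E13.5, in days of embryonic development, in 2 groups of 4 libraries each. Mutant kidneys carried Foxd1Cre, which expresses Cre recombinase in renal stromal progenitors, with a floxed and a null copy of Smo. Smo encodes Smoothened, the membrane protein that passes the hedgehog signal into the cell. Control kidneys carried a floxed and a wild type copy of Smo. The comparison asked which transcripts differ in the kidney when stromal progenitors and their descendants lose Smo. Mutants also lacked 1 copy of Smo in every cell and carried the Cre allele, so each difference belongs to the whole genotype. Libraries held 10288191 to 13494079 reads in genes. The table listed 23337 genes, of which 13692 had a mean normalised count of at least 10 and were tested. Levels are normalised read counts given as mean ± SD with n = 4 per group. Fold changes are log2 of mutant over control on the scale of normalised count + 1, which understates changes of low genes. Adjusted p-values are from limma with Benjamini-Hochberg adjustment unless stated. The labels number the samples 1 to 4 and do not say that they came from separate embryos or litters, so p-values measure only the spread between these samples.

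Smo itself, on chromosome 6 from 29735497 to 29761366 of GRCm38, fell from 2241 ± 66.4 in control to 537 ± 20.01 in mutant kidneys. That was 24.0% of the control level and a log2 fold change of -2.06 (SE 0.041, adjusted p = 1.87e-10). Control libraries lay between 2152 and 2294 and mutant libraries between 509 and 553, so each library matched its label. An exact two-sided permutation test gave p = 0.0286, the smallest that 70 arrangements allow. Smo remained past the threshold with each library left out in turn, with fold changes from -2.08 to -2.03.

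In the list of hedgehog targets, 3 of 15 tested genes were lower in the mutants. Gli1, a transcription factor that is itself switched on by the pathway, fell from 413 ± 36.2 to 259 ± 29.4 (log2 fold change -0.68, SE 0.092, adjusted p = 0.0102). Ccnd2, which encodes cyclin D2, fell from 7930 ± 337 to 6774 ± 257 (log2 fold change -0.23, adjusted p = 0.0309). Igfbp6, an insulin-like growth factor binding protein, fell from 87.4 ± 33.3 to 25.8 ± 4.5 (log2 fold change -1.62, adjusted p = 0.0437). Of 15 tested members of the hedgehog target list these 3 passed over all genes and 12 did not. Adjusted over the list alone, 8 members were lower and 1 was higher, the latter being Bcl2, an inhibitor of apoptosis named here after its values were seen (log2 fold change 0.25, adjusted p = 0.168 over all genes). For Ptch1, the main hedgehog receptor gene, the level was 716 ± 155 in control and 506 ± 30.1 in mutant kidneys (log2 fold change -0.48, adjusted p = 0.164). Ptch1 passed without control 4 (adjusted p = 0.0348) and in none of the other fits that left out 1 library. Without controls 1 and 2, a setting chosen after seeing the data, its log2 fold change was -0.20 (adjusted p = 0.369). For Hhip, which encodes a secreted hedgehog-binding inhibitor, the log2 fold change was -0.24 (adjusted p = 0.739). The list as a whole was lower by camera, with a mean log2 fold change of -0.31 (adjusted p = 2.57e-07), and its score was lower in all 4 mutants than in all 4 controls (exact permutation p = 0.0286). With an estimated correlation between members, the list's call was lost (adjusted p = 0.0539 with an estimated correlation). Leaving out control 3 ended the call of Gli1 (adjusted p = 0.0517), whose exons overlap those of Arhgap9 on the opposite strand. The calls of Ccnd2 and Igfbp6 were lost in 5 and 7 of the 8 fits that left out 1 library, with adjusted p up to 0.133 and 0.165, both without control 3.

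**Figure D1:**
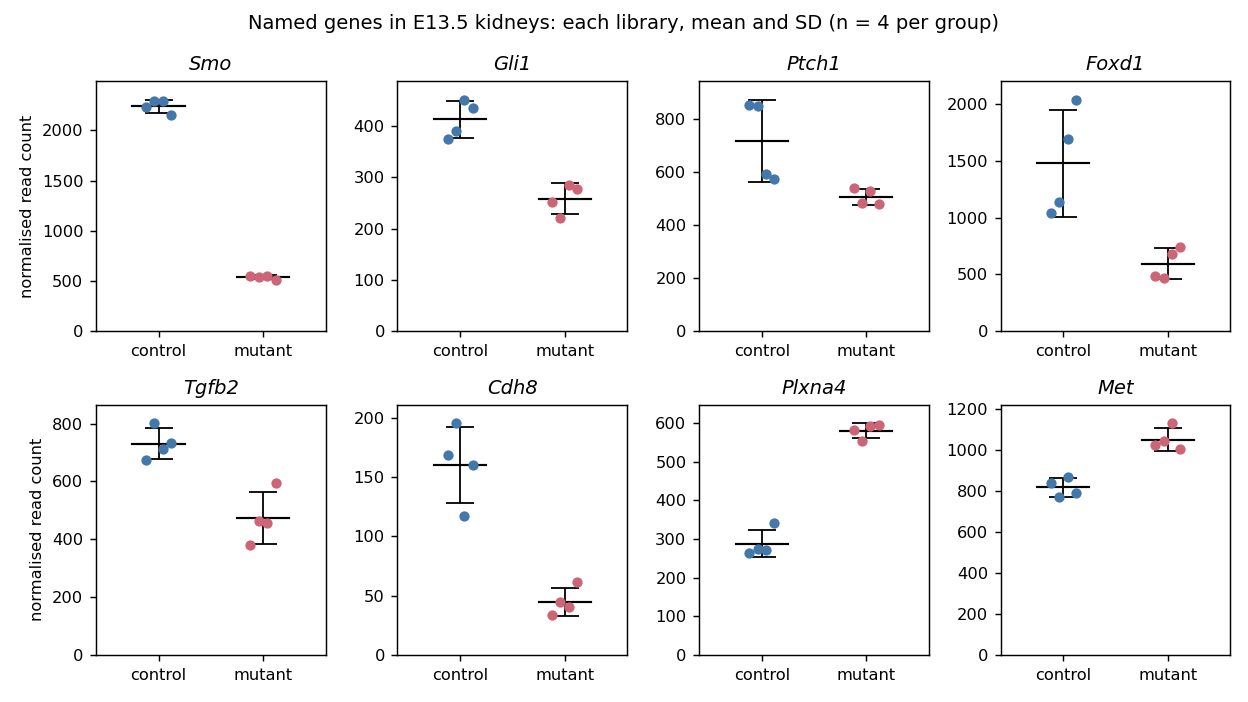
Normalised read counts (y axis, from 0) of 8 named genes in control and mutant kidneys; each point is 1 library, and bars give the mean and SD with n = 4 per group. Smo, Gli1, Foxd1, Tgfb2 and Cdh8 were lower and Plxna4 and Met higher in all 4 mutants than in all 4 controls, while Ptch1, also lower in all 4 mutants, did not pass the test (adjusted p = 0.164).

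Across the transcriptome 78 genes changed, 61 lower and 17 higher in mutant kidneys. The median log2 fold change of all tested genes was 0.0037. After Smo, the largest falls among genes with a mean of at least 50 were in Rxfp2, the receptor for insulin-like peptide 3 (202 ± 41.4 to 56.8 ± 20.8, log2 fold change -1.87, adjusted p = 0.0102), and in Cdh8, a type II cadherin (160 ± 32.4 to 44.9 ± 11.8, log2 fold change -1.82, adjusted p = 0.0062). Igfbp6, Slitrk6, Foxd1, Tmtc1, Smoc2, Kcnd2 and Thy1 followed, with log2 fold changes from -1.62 to -1.01. Slitrk6 encodes a leucine-rich repeat transmembrane protein, Kcnd2 a potassium channel and Thy1 a surface glycoprotein. The 5 falls with the smallest p included Smo and Cdh8 and those in Pcsk5, a proprotein convertase (589 ± 29.3 to 420 ± 22.05), Sertad4 (530 ± 29.4 to 370 ± 21.5) and Thsd7a (159 ± 17.9 to 82.1 ± 7.8), each with an adjusted p of 0.0064. Only 1 gene rose by more than 1 on the log2 scale, Plxna4, a semaphorin co-receptor, which went from 288 ± 35.3 to 580 ± 19.2 (log2 fold change 1.02, SE 0.078, adjusted p = 0.00028). In contrast, 13 genes fell by more than that. Plxna4 lies 2.62 Mb from Smo on chromosome 6. The other leading rises were smaller, from 0.61 for Cntn4, an axonal adhesion protein, to 0.32 for Pax2, a transcription factor of the nephric lineages. They included Pid1 (0.45), Sel1l3 (0.39), the kinesin Kif26b (0.38), the proteoglycan Spock2 (0.38), Met, the receptor for hepatocyte growth factor (0.36), the clathrin adaptor Snap91 (0.36) and Fam132a (0.32), now called C1qtnf12. Met rose from 817 ± 44.8 to 1050 ± 55.5 (adjusted p = 0.0130).

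All 78 genes separated the 4 mutants from the 4 controls without overlap. Of all tested genes 5.31% did so, against 2.86% expected by chance. An unadjusted p under 0.05 was reached by 1191 genes. The number of calls depended on single libraries. It was 46 without control 1, 31 without control 2, 18 without control 3, 185 without control 4, 28 without mutant 1, 25 without mutant 2, 20 without mutant 3 and 104 without mutant 4. All 78 kept their direction in each of these fits. Of the 34 called genes named in the text, 9 (Smo, Plxna4, Cdh8, Spock2, Pcsk5, Sertad4, Thsd7a, Mdfic and Lhfpl2) passed in every such fit. Among them Plxna4, Thsd7a, Mdfic and Lhfpl2 lie within 20 Mb of Smo or Foxd1, and Mdfic and Lhfpl2 were named after their positions were seen. Another 6 (Gli1, Rxfp2, Itga8, Thy1, Met and Pid1) lost the call in 1 to 3 fits and 19 in 4 or more, with adjusted p no higher than 0.165 and most often highest without control 3 or mutant 3. The authors' deposited table listed 117 genes at an adjusted p under 0.05, 24 higher and 93 lower, of which 72 were also called here, all in the same direction.

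**Figure D2:**
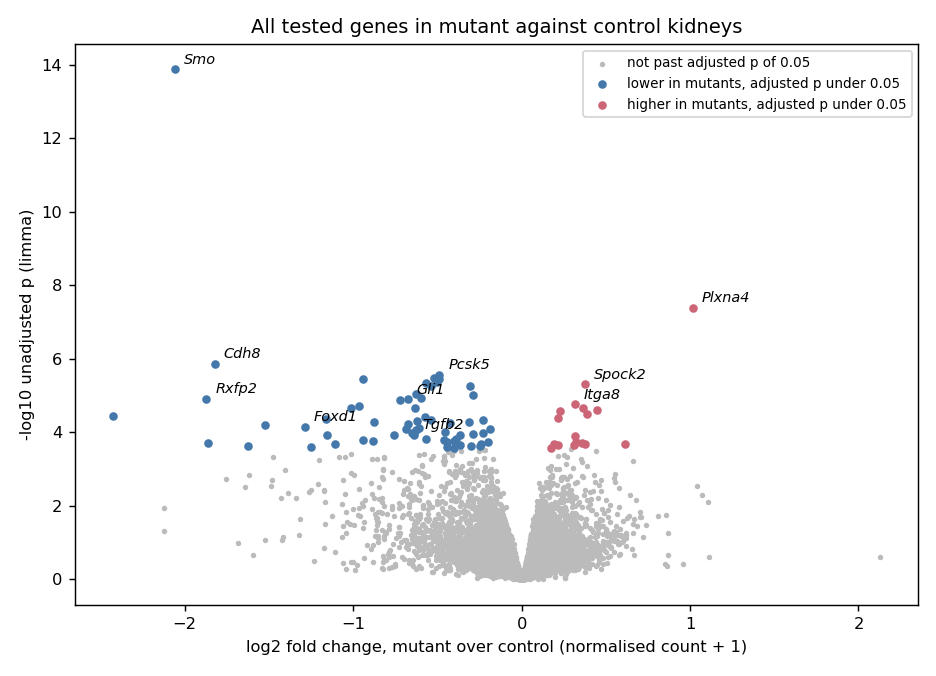
Log2 fold change (x axis) against -log10 of the unadjusted limma p (y axis) for the 13692 tested genes, with 61 genes lower (blue) and 17 higher (red) at an adjusted p under 0.05. Smo and Plxna4 had the smallest p in either direction.

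In the list of the renal cortical stroma, the layer that expresses Foxd1, 2 of 19 tested genes were lower. Foxd1, a transcription factor of stromal progenitors, fell from 1477 ± 473 to 593 ± 137 (log2 fold change -1.29, SE 0.212, adjusted p = 0.0251). Smoc2, a secreted matrix-associated protein, fell from 975 ± 230 to 441 ± 121 (log2 fold change -1.15, adjusted p = 0.0325). Values for Ntn1, which encodes the guidance cue netrin 1, were 2216 ± 453 and 1266 ± 292 (adjusted p = 0.0680), and those for the Wnt inhibitor gene Sfrp1 were 3130 ± 228 and 2401 ± 332 (adjusted p = 0.0876). The other 17 did not pass over all genes, 7 members were lower adjusted over the list alone, and 4 of the 19 had positive fold changes. The list had a mean log2 fold change of -0.32 by camera (adjusted p = 1.30e-06, adjusted p = 0.168 with an estimated correlation, and adjusted p = 0.103 by fry). The commonly used Foxd1Cre allele is an insertion that disrupts Foxd1, and the labels do not name the allele, so the level of Foxd1 cannot by itself be read as a measure of stromal cells. The list's mean and score include Foxd1 and share this limit. Control 4 had the lowest control score (0.01, against -0.03 in mutant 4) and the highest Foxd1 level (2039). The separation of the scores was not tested without Foxd1. The list kept its camera call without genes within 20 Mb of Smo and Foxd1, Foxd1 included, a setting chosen after seeing the data. Foxd1 lost its call without control 3 (adjusted p = 0.109), mutant 1 (0.0982), mutant 2 (0.0897) or mutant 3 (0.0715), and Smoc2 in 5 fits (adjusted p up to 0.129, without mutant 3).

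In the list of transforming growth factor beta signalling, 2 of 19 tested genes were lower. The ligand genes Tgfb2 (731 ± 52.9 to 474 ± 89.2, log2 fold change -0.64, adjusted p = 0.0325) and Tgfb3 (673 ± 57.9 to 439 ± 69.2, log2 fold change -0.62, adjusted p = 0.0207) fell. Ltbp3, which encodes a latent TGF-beta binding protein, had a log2 fold change of -0.27 (adjusted p = 0.107), and the co-receptor gene Tgfbr3 one of -0.28 (adjusted p = 0.406). Of 19 tested members 2 were called, 17 were not, and 3 were lower adjusted over the list alone. The list's mean log2 fold change was -0.24 by camera (adjusted p = 4.67e-07, and adjusted p = 0.0539 with an estimated correlation). Tgfb2 lost its call in 6 of the 8 fits with 1 library left out (adjusted p up to 0.120) and Tgfb3 in 5 (up to 0.0913), both highest without mutant 3.

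In 2 lists of progenitor compartments, 2 of 20 and 1 of 16 genes were higher in the mutants. Nephron progenitors are the cap mesenchyme cells that form the nephron. Among their 20 tested genes Spock2 rose from 2601 ± 166 to 3373 ± 114 (log2 fold change 0.38, adjusted p = 0.0064) and Itga8, the integrin subunit that binds nephronectin, from 1648 ± 79.0 to 2049 ± 86.7 (log2 fold change 0.31, adjusted p = 0.0126). Log2 fold changes were 0.44 for Meox2 (adjusted p = 0.0521) and 0.35 for Six2, the transcription factor that maintains these cells (1678 ± 190 and 2138 ± 135, adjusted p = 0.0693). The other 18 members were not called over all genes, and 6 were higher adjusted over the list alone. The list's mean log2 fold change was 0.21 by camera (adjusted p = 3.00e-10, and adjusted p = 0.0539 with an estimated correlation). In the ureteric bud tip list of 16 genes, Gfra1, the co-receptor for glial cell line-derived neurotrophic factor, rose from 1568 ± 111 to 1947 ± 126 (log2 fold change 0.31, adjusted p = 0.0424). Spry1, an inhibitor of receptor tyrosine kinase signalling (0.27, adjusted p = 0.0656), the transcription factor gene Etv5 (0.24, adjusted p = 0.133) and the receptor gene Ret (0.33, adjusted p = 0.142) did not pass over all genes. Adjusted over the list alone, 7 members were higher. The list's mean log2 fold change was 0.22 by camera (adjusted p = 4.37e-09, adjusted p = 0.131 with an estimated correlation, and adjusted p = 0.0575 by fry). Gfra1 lost its call in 6 fits with 1 library left out (adjusted p up to 0.155, without mutant 3). Itga8 lost its call without mutant 2 or mutant 3 (adjusted p up to 0.0574), and its exons overlap those of the antisense gene E030013I19Rik.

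**Figure D3:**
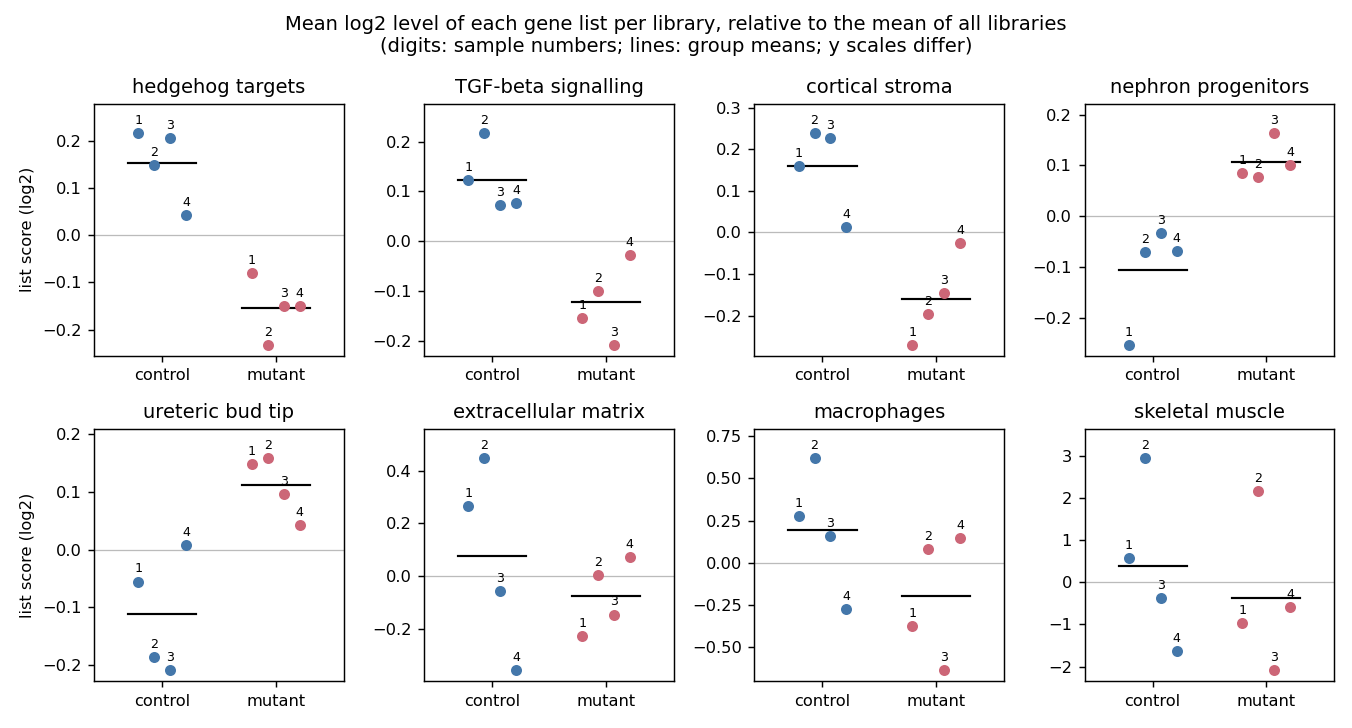
Scores of 8 gene lists per library (y axis, mean log2 level of the tested members relative to the mean of the 8 libraries, with scales that differ between panels); digits are sample numbers and lines are group means. The 5 lists of hedgehog targets, TGF-beta signalling, cortical stroma, nephron progenitors and ureteric bud tip separated the groups, and the extracellular matrix, macrophage and skeletal muscle lists did not. The cortical stroma score includes Foxd1, which the Cre allele may disrupt, and its separation was not tested without Foxd1.

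The other lists called by camera had few or no called members. Macrophage genes had a mean log2 fold change of -0.39 with none of 16 called (adjusted p = 3.21e-05, and adjusted p = 0.589 with an estimated correlation), led by Laptm5 (114 ± 9.9 and 74.1 ± 23.1, adjusted p = 0.219). The macrophage list lost its call without controls 1 and 2 (adjusted p = 0.285). Hypoxia and glycolysis genes had a mean of 0.15 with none of 16 called and 4 higher adjusted over the list alone (adjusted p = 2.29e-06, and adjusted p = 0.266 with an estimated correlation). These were Ldha, Aldoa, Pgk1 and Bnip3, with log2 fold changes from 0.17 to 0.26. In the extracellular matrix list Fn1, which encodes fibronectin, fell from 8524 ± 328 to 6375 ± 716 (log2 fold change -0.43, adjusted p = 0.0218), while 21 of 22 members were not called and 2 were lower and 1 higher adjusted over the list alone. Fn1 lost its call in 4 fits with 1 library left out (adjusted p up to 0.0966, without control 3). The matrix list had a mean of -0.15 (adjusted p = 0.0079, and adjusted p = 0.725 with an estimated correlation) and lost its call without control 1 (adjusted p = 0.155), control 2 (0.534), mutant 1 (0.0945) or the libraries numbered 2 (0.268), and with the muscle score as a covariate (mean -0.07, adjusted p = 0.137). Its direction was opposite without controls 1 and 2 together (mean 0.13, adjusted p = 0.0278). Smooth muscle genes had a mean of -0.15 with none of 14 called and 2, Tpm1 and Mylk, lower adjusted over the list alone (adjusted p = 0.0177, 0.360 as adjusted p with an estimated correlation, 0.0519 as adjusted p without control 2, and 0.285 as adjusted p without controls 1 and 2). Endothelial genes had a mean of -0.08 with none of 18 called (adjusted p = 0.0358, and adjusted p = 0.725 with an estimated correlation), and lost their call without control 1 (adjusted p = 0.325), control 2 (0.137), mutant 3 (0.918), mutant 4 (0.0543), controls 1 and 2 (0.894) or the libraries numbered 2 (0.0502), and with the muscle score as a covariate (mean -0.06, adjusted p = 0.227). In all, 10 of 33 lists passed by camera with the preset correlation and 0 with an estimated one, where 6 had an unadjusted p under 0.05. The setting with an estimated correlation changed more than the correlation, as set out below. The self-contained test fry found 3 lists that moved one way, those of hedgehog targets, TGF-beta signalling and nephron progenitors (adjusted p = 0.0177 each), and its mixed form, which takes changes in either direction, passed 9.

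Libraries differed in transcripts of tissues around the kidney. The skeletal muscle myosin gene Myh3 stood at 1105 in control 2, 694 in mutant 2 and 169 in control 1, and between 3.4 and 59.1 in the other libraries. The liver transcript Alb stood at 259 in control 1 and at 2.8 to 45.8 in the others. Control 2 and control 1 also had the highest scores of the extracellular matrix list (0.45 and 0.27), and control 4 the lowest (-0.36). Apart from surrounding tissues, libraries differed in sex. Y-linked Ddx3y was at 1518 in control 4 and 1390 in mutant 2 and at no more than 1.7 in the other libraries. Xist, a transcript of female cells, was at 16.9 in control 4 and 23.4 in mutant 2 and at 26989 to 39486 in the others. By these levels control 4 and mutant 2 were male and the other libraries female. Without both libraries numbered 2, which held the most muscle RNA, 2 genes were called, Smo and Plxna4, a setting chosen after seeing the data, like those without controls 1 and 2 and with the muscle score. Plxna4 lies 2.62 Mb from Smo.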

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

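Of 212 groups of 4 values tested for a library far from the other 3, 7 stood out, where chance gives about 10.6. In control 4, Igfbp6 was 37.6 against 101 to 108 in the other controls, and Plxna4 was 340.3 against 265 to 274. In control 1, Calb1 was 3018 against 2143 to 2220, Kirrel was 1570.2 against 1627 to 1635, and the score of the nephron progenitor list was -0.25 against -0.07 to -0.03. In mutant 4, Tmtc1 was 139 against 115 to 118, and in mutant 3, Fgf10 was 335 against 319 to 321.

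Other splits of the 8 libraries into 4 and 4 were counted for each result over many genes, which makes 35 splits with the real one included. The real split was the only one of the 35 to reach 78 calls, where the highest of the others gave 21. That makes chance unlikely for the count, although 1 of 35 is the smallest share this test can give. Likewise 1 of 35 splits reached 17 genes in the higher direction and 1 reached 61 in the lower, where the highest of the other splits gave 12 in either direction. The split with 21 calls set the libraries numbered 1 and 2 of both groups against those numbered 3 and 4. For the hedgehog target list 1 of 35 splits had a mean change as large (0.31, highest other 0.24). This had to follow from the separation of its scores given above, so it adds no further support. For the number of lists called, 8 of 35 splits reached the real value of 10 and the highest other gave 16, so chance cannot be excluded for that count. In 4 of the 5 splits with more lists, control 4 was grouped with mutant libraries.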

How the results depend on the processing

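Leaving out controls 1 and 2, leaving out the libraries numbered 2, the muscle and Y-linked covariates and the fit without genes near Smo and Foxd1 were chosen after seeing the data. The directions of all 78 called genes held under every alternative in which they were tested. Counts of higher and lower genes stayed within 1.5 times under both pseudocounts, both filters, both rescalings, robust empirical Bayes, edgeR (79 calls, 78 shared), without X and Y genes, with a muscle or Y-linked score as covariate, and without genes near Smo and Foxd1. Array weights gave 38 higher and 116 lower, and DESeq2 on recovered reads gave 54 and 160 (14 genes had no adjusted p), in both cases including all 78. With 1 library left out, higher genes ranged from 3 to 55 and lower genes from 13 to 130. Leaving out controls 1 and 2 gave 6 higher and 23 lower, and leaving out the libraries numbered 2 gave 1 higher and 1 lower. Fewer samples lower the power of these fits, but 185 calls without control 4 show that the libraries did not weigh alike, and the cause was not tested.

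With the sample number as a block, 62 genes were higher and 170 lower, all 78 among them, and 12 lists passed. Deviations of same-numbered libraries correlated at 0.325, 0.287, 0.294 and 0.0635 for numbers 1 to 4. Numbers 1 to 3 each correlated best with their own number. The correlation for number 4 lay below the 0.1 set for pairing, and the libraries numbered 4 correlated best with number 3 of the other group, so the numbers were not taken to pair the samples. The block added 25 of the 61 uncalled genes followed one by one, Ptch1 among them (adjusted p = 0.0372), and removed none. Foxd1 varied with the number in both groups. For numbers 1 to 4 it was 1038, 1138, 1693 and 2039 in controls and 484, 469, 682 and 738 in mutants. Its adjusted limma p with the block was 3.35e-06. Fits without the block count such shared spread as noise, which bears on the calls of Foxd1 lost with 1 library left out.

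The count of lists was 0 with an estimated correlation and 3 by fry, and 7 to 15 with 1 library left out. The hedgehog target list missed the threshold with an estimated correlation (adjusted p = 0.0539), a setting that leaves its mean of -0.31 as it is and put 0.0356 in place of the preset 0.01. The setting also changed the test in another way. The p53 list had an estimated correlation of -0.046, below the preset, yet its unadjusted camera p rose from 0.135 to 0.163. The lost calls therefore cannot be laid to the correlation alone, and how far that value alone ended the call of the hedgehog list was not tested. The hedgehog target list passed in each of the other settings run for it (adjusted p 4.82e-08 to 0.0177), with a mean of -0.34 to -0.28 when 1 library was left out. The extracellular matrix list turned to 0.13 without controls 1 and 2, which hold its highest scores, and the cause was not tested. Of the lists not called at first, 5 passed without control 4 and at most 3 in any other setting. Of the 94 genes besides Smo that were followed one by one, none changed direction in 1682 values, 180 of which lost and 56 gained a call. This set left out 53 list members after all values had been seen, and 18 of those changed sign under at least 1 alternative. The absence of sign changes therefore holds for the chosen genes only. Low depth limits genes near a mean of 10, which the log scale compresses.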

Other observations

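The tests on position, cell shares, stage, muscle peaks, the muscle covariate and the difference of 2 list scores were chosen only after seeing the data, while the rescaling was planned.

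By camera 23 lists were not called with all 8 libraries (adjusted p from 0.140 to 0.929), and single libraries decided this for 7 of them. Without control 4, committing nephron (mean log2 fold change -0.23, adjusted p = 0.0212), medullary stroma (-0.24, 0.0016), pericytes (-0.13, 0.0358), podocytes (-0.19, 0.0098) and skeletal muscle (-1.42, 0.0038) passed. Ureteric trunk passed without control 1 (0.14, adjusted p = 0.0026) or mutant 4 (0.11, 0.0183), skeletal muscle also without control 3 (-1.004, 0.0357) or mutant 2 (-1.60, 2.55e-05), and red cells without mutant 3 (0.75, 0.0062). Without controls 1 and 2, a setting chosen after seeing the data, committing nephron passed in the opposite direction (0.25, adjusted p = 0.0248). In that setting ureteric trunk (0.25, adjusted p = 7.91e-06) and liver (1.42, adjusted p = 0.0099, with 4 tested members) passed as well. With all libraries, of their 288 memberships 1 was called higher (Itga8, which the pericyte list also holds) and 1 lower (Jun, an immediate early gene, 700 ± 67.7 in control and 542 ± 22.8 in mutant kidneys, adjusted p = 0.0430 and up to 0.158 with 1 library left out), with 8 higher and 13 lower adjusted over the list alone. With all libraries medullary stroma had a mean log2 fold change of -0.12, hedgehog ligands, receptors and components -0.06, podocytes -0.08, committing nephron -0.06, proximal tubule -0.06, ureteric trunk 0.05, pericytes and mesangium -0.01 and ureteric mesenchyme -0.01. Among pathways the mean was -0.09 for Wnt, -0.06 for BMP and FGF signals and -0.04 for retinoids. It was 0.02 for proliferation, -0.05 for p53 targets and -0.08 for immediate early genes. Lists of other tissues stood at -0.75 for skeletal muscle, 0.44 for red cells, -0.15 for gonad, 0.06 for neurons, 0.05 for adrenal, -0.05 for cartilage, -0.04 for fat, -0.01 for liver and 0.10 for sex-linked genes. Mean, median and test differed in sign for 6 lists, those of BMP and FGF signals, cartilage, liver, neurons, ureteric mesenchyme and Wnt. Adjusted over the retinoid list alone, Crabp1, a retinoic acid binding protein gene (1045 ± 211 and 616 ± 146), Aldh1a2 and Rarres2 were lower and Ecm1 was higher, none of them called over all genes.

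The odds ratio of a call near Smo against elsewhere was 6.12 within 20 Mb (95% interval 1.90 to 15.3, Fisher's exact test) and 4.28 within 10 Mb (0.501 to 16.5), and near Foxd1 it was 2.84 within 20 Mb (0.334 to 10.9). Within 20 Mb of Smo on chromosome 6 lay Thsd7a, Mdfic, Met, Kcnd2 and Plxna4, and within 20 Mb of Foxd1 on chromosome 13 lay Lhfpl2 and F2r. Mdfic, Lhfpl2 and F2r were named after their positions were seen. Together these were 7 of 292 tested genes (2.40%) against 68 of 13302 elsewhere (0.511%), an odds ratio of 4.78 (95% interval 1.84 to 10.5, Fisher's exact test), with 3 higher and 4 lower. A candidate explanation is strain variants linked to the modified alleles, for which the odds ratio against the rest of chromosomes 6 and 13 was 5.49 (95% interval 1.38 to 25.8), with 3.15 (0.670 to 12.6) at 10 Mb and 2.35 (0.593 to 11.0) at 40 Mb. Chance position and an effect of lost signal alone cannot be told apart from it, because the share of rotations of the gene order with as many calls was 0.0280 at 20 Mb but 0.0545 at 10 Mb and 0.0661 at 40 Mb (for Smo alone 0.0188, 0.0972 and 0.0360), and the window was set after the positions had been seen.

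The cortical stroma list was lower while nephron progenitor and ureteric tip lists were higher. A single scaling factor per library moves all lists alike, so the distance of 0.532 between the changes of nephron progenitors and cortical stroma, larger than the SD within either group (0.138 and 0.0993), argues against it. The planned rescaling, by upper quartile or quantiles, moved the lists by at most 0.0144 and turned 0 directions. Quantile normalization takes out scaling that depends on level alone. After it cortical stroma stood at -0.314, nephron progenitors at 0.225 and ureteric tip at 0.232. These means argue against such scaling for these lists. A smaller share of stromal cells could lower stromal and raise all other transcripts. In the cortical stroma list 15 log2 fold changes were negative and 4 positive. Members such as Meis1 (-0.048, SE 0.088), Meis2 (0.025, SE 0.064), Tcf21 (0.020, SE 0.071) and Dchs1 (-0.0035, SE 0.084) hardly changed. The list thus did not fall evenly, which was not tested against a smaller share. Endothelial and podocyte lists did not rise (-0.08 each), but these changes were smaller than the SD among controls (0.0912 and 0.237). The score of nephron progenitors minus that of 4 other renal cell lists was 0.255 higher in mutants (exact permutation p = 0.229). That leaves a smaller share of stromal cells open. An earlier stage stays open too, with differentiated cell lists at -0.0359 in mutants against controls (exact permutation p = 0.886). Both cannot be told apart from altered gene activity within stromal cells, since both differences are smaller than the SD among controls (0.315 and 0.346). By sample number, mutant minus control was 0.428, 0.233, 0.379 and -0.0201 for the progenitor difference, for numbers 1 to 4. For the differentiated cell lists it was -0.145, -0.135, -0.129 and 0.266. So 3 of 4 shared a sign in each and number 4 went the other way, but the numbers were not taken to pair the samples.

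Skeletal muscle transcripts varied between libraries of both groups. All 6 abundant sarcomere transcripts examined (Myh3, Acta1, Mylpf, Myl1, Tnnc2 and Actc1) were highest in control 2, which is consistent with muscle tissue carried over at dissection. None of the 11 tested members of the muscle list was in another list, and 5 of them were above 10 in every library. The muscle score overlapped between groups (0.38 ± 1.93 in control and -0.38 ± 1.80 in mutant libraries), while all 78 called genes separated them. So carry-over in proportion to this score did not account for the calls of single genes. With the score as a covariate the median ratio of the 78 log2 fold changes to those without it was 0.983, with a range of 0.888 to 1.09. This ratio had little room to move, since the genes were called for a small spread within groups. Without the libraries numbered 2 the median ratio was 0.972, with a range of 0.823 to 1.15 and all 78 in the same direction, although 2 calls were left at 3 against 3. Without controls 1 and 2 it was 0.992, with a wider range of 0.640 to 1.30 and all 78 in the same direction. The calls of the matrix and endothelial lists were lost with the covariate (adjusted p = 0.137 and 0.227).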
